A study of Mus musculus with 16 samples.

How the data were processed

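Per the labels' protocols, macrophages were isolated from lavage fluid, total RNA was extracted with the RNeasy Mini kit and TruSeq mRNA libraries were sequenced as paired reads of 50 bases. Per the submitters' processing notes, reads were checked with FastQC 0.11.3 and aligned to mm10 with TopHat2 2.0.13 and Bowtie2 2.2.1, and Cufflinks and Cuffdiff 2.1.1 were also run. The table deposited by the authors holds counts per gene symbol, made with HTSeq as its name states, as whole numbers without normalization. The HTSeq version, its strand setting and the gene annotation were not given in the sources used here, so counts of multicopy genes and of genes that overlap on opposite strands are uncertain. Cuffdiff values were not used here.

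All 16 columns were assigned to the 4 groups by the labels. No pair of libraries within a group was a copy of another: the chi-square per degree of freedom between libraries, over genes with at least 10 counts, lay between 8.0 and 302.8. The 10 most abundant genes held between 12.8% and 18.3% of each library. Gene positions came from GENCODE mouse M21 (mm10) by symbol, and 22648 of 23159 symbols had a position, of which some were matched through an older symbol.

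Genes were kept by filterByExpr with a minimum count of 10 on the 4 groups, which left 12455 and removed 10704. Counts were scaled by TMM (factors 0.9 to 1.07) and fitted in edgeR 4.0.16 (R 4.3.3) by a quasi-likelihood model with 1 coefficient per group. The biological coefficient of variation was 0.238. The contrasts were injured against control in each genotype, TLR3-KO against WT in each state, and the difference of the pneumonia responses. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. CPM values in the text use raw library totals and are means with SD over 4 libraries, and fold changes are those of the edgeR fit. The SE of a log2 fold change is its size divided by the square root of the F statistic.

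Of 35 gene lists, 33 were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation. The other 2 lists, ribosomal proteins and genes of the mitochondrial genome, matched no symbol and were not analysed here. Summed CPM of marker lists were compared by two-sided exact permutation tests. Calls within 10 Mb of Tlr3 were compared with calls elsewhere by a two-sided Fisher's exact test. The model, the lists, the distance and the rule for naming genes were set before the data were examined. The rule named, per contrast, the 8 highest and 8 lowest fold changes among called genes with a group mean of at least 5 CPM and no overlap between groups, or the 5 lowest p-values where none passed, and up to 4 members of each list described.

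The sample titles number the replicates of each group. Whether the numbers pair libraries was checked by correlating each library's departure from its group mean with those of the other group. Between control genotypes the correlation at the same number was 0.48 to 0.60, and 7 of 8 libraries matched their own number best, so the blocked count is given beside the unblocked one. After pneumonia in TLR3-KO the correlations were -0.07 to 0.34 and 6 of 8 libraries did so, and in the other contrasts 0 of 8 did. The model was tested on simulated data in which 200 genes were changed, beside a list raised 1.5-fold that was not counted as false. Of the 200 it recovered between 72.7% and 89.4% of 4-fold changes, between 32.8% and 62.7% of 2-fold changes and between 1.5% and 28.4% of 1.5-fold changes, with 1.4% to 4.9% false calls. Genes were drawn independently, with no replicate pairing, sex difference or other structure shared by libraries. These rates therefore need not hold for the real libraries. The alternatives were RLE size factors, DESeq2 1.42.0, limma voom, other filters, fits of 2 groups, the replicate number as a block, each library left out in turn, and, chosen after seeing the data, the sex of the RNA, subsets of the controls and voom with equal weights. Tables and figures were made with python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.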

Results

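RNA from macrophages recovered by bronchoalveolar lavage, a saline wash of the airways, was sequenced from wild-type (WT) mice and from mice lacking Toll-like receptor 3 (TLR3-KO). TLR3 is an endosomal receptor of the innate immune system that senses double-stranded RNA. In each genotype, control mice were set beside mice sampled following pneumonia, a group the sample titles call injured. Per the labels' protocols, mice received 500 CFU of Klebsiella pneumoniae in 30 µl, or saline, through the hypopharynx, while the treatment label of the controls reads none. The table holds 4 libraries in each of 4 groups, 16 in all, although the series text counts 15. Total counts per library lay between 29667102 and 59640251 over 23159 gene symbols, of which 12455 passed the expression filter and were tested. The labels do not say whether each library came from a separate mouse, so the p-values measure the spread between libraries. The time after infection was not given in the sources used here.

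Tlr3 counts followed the genotype labels in every library. The gene (ENSMUSG00000031639.12) lies on chromosome 8 from 45395665 to 45411080 in mm10. In controls it was counted at 0.529 ± 0.211 CPM in TLR3-KO and 3.48 ± 1.23 CPM in WT (SD, n = 4 each), so the TLR3-KO level was 15.2% of the WT level. In injured mice the levels were 0.491 ± 0.135 CPM and 3.44 ± 0.85 CPM, or 14.3%. The genotypes did not overlap in either state (exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow). TLR3-KO libraries held 13 to 34 Tlr3 reads each, and gene totals do not show from which exons these came.

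The sex of the RNA was not the same throughout, although the series title speaks of male mice. Xist, the RNA that silences an X chromosome in female cells, was counted at 42.3, 31.6 and 20.3 CPM in TLR3-KO controls 1, 2 and 3, and at no more than 0.23 CPM in the other 13 libraries. Summed over Ddx3y, Eif2s3y, Kdm5d and Uty, 4 genes of the Y chromosome, these 3 libraries reached 0.4%, 0.6% and 12% of the median library, while the lowest of the other 13 reached 84.3%. Every comparison that uses the TLR3-KO controls therefore sets 3 libraries with Xist and 1 without against libraries without Xist.

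**Figure D1:**
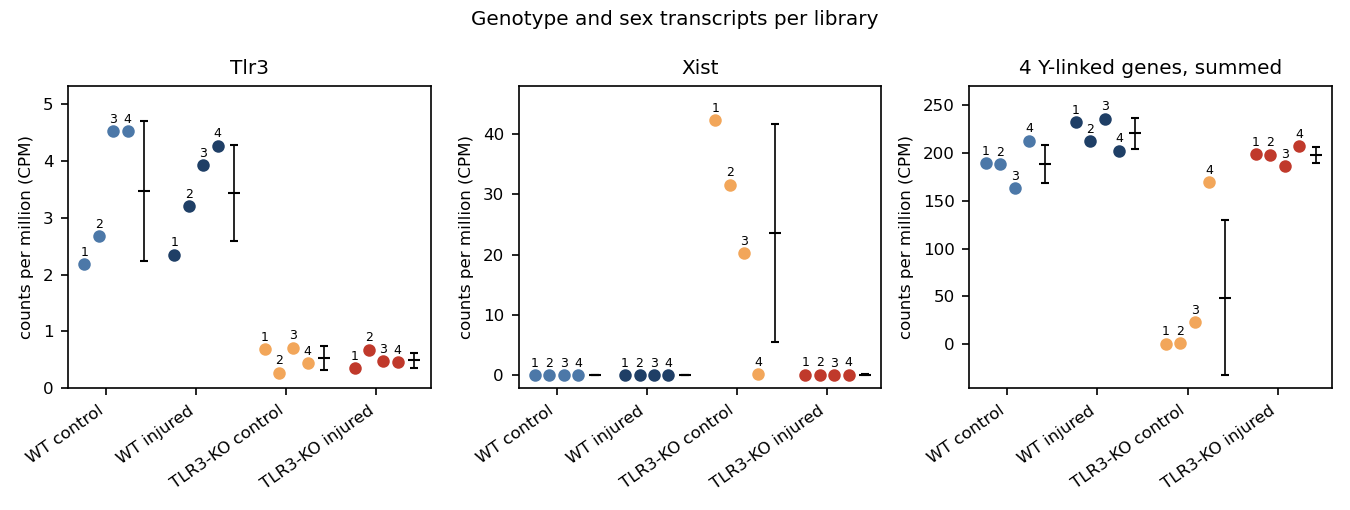
CPM of Tlr3, of Xist and of 4 Y-linked genes summed, in each of the 16 libraries; points are libraries with their replicate number, and the black bars give the mean and SD of each group of 4. Tlr3 is lower in all TLR3-KO libraries, and TLR3-KO controls 1, 2 and 3 show Xist with few Y-linked counts.

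The first principal component of log2 CPM held 27.5% of the variance and did not part the groups. It placed controls 1 and 2 of both genotypes on one side and controls 3 and 4 of both genotypes on the other. Cxcl2 and Tnf, chosen after their values were seen, differed along the same line, while Clec4e and Il1rn of the same gene list did not in TLR3-KO controls. Cxcl2, a chemokine that attracts neutrophils, was counted at 813 and 701 CPM in WT controls 1 and 2 but at 45.4 and 68.2 CPM in WT controls 3 and 4. In TLR3-KO controls 1 to 4 it was counted at 279, 158, 65.9 and 62.1 CPM. Tnf was counted at 489, 384, 59.9 and 93.9 CPM in WT controls 1 to 4, and at 301, 186, 48.6 and 122 CPM in TLR3-KO controls 1 to 4.

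**Figure D2:**
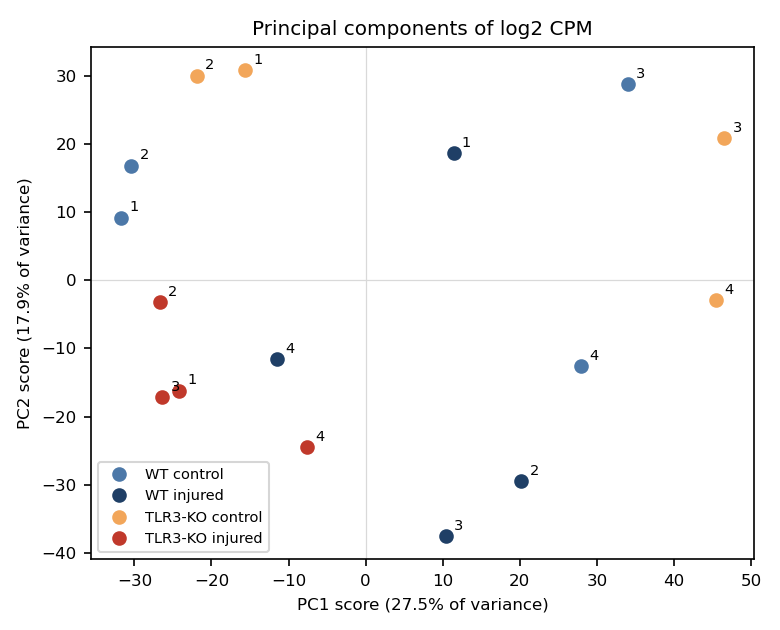
Scores of the 16 libraries on the first principal component (x axis, 27.5% of the variance) and the second (y axis, 17.9%) of log2 CPM; each point is a library with its replicate number, coloured by group. Controls 1 and 2 of both genotypes lie at negative scores on the first component and controls 3 and 4 at positive scores.

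The first comparison asked which genes changed in WT macrophages following pneumonia. Genes of cholesterol biosynthesis fell together. The median log2 fold change of the 24 measured members was -0.67, and 23 of them were lower in injured libraries. Cyp51, the sterol demethylase, was counted at 412 ± 75.1 CPM in injured and 619 ± 38.8 CPM in control libraries (SD, n = 4 each; log2 fold change -0.70, SE 0.12). Hmgcs1, which makes the precursor of mevalonate, was counted at 472 ± 99.3 and 737 ± 35.9 CPM, and Hsd17b7, another enzyme of sterol synthesis, at 72.5 ± 16.7 and 119 ± 8.29 CPM. The list fell with an adjusted p of 1.39e-33 (camera, preset correlation 0.01), and the call held with an estimated correlation (adjusted p = 0.0214). No member passed over all genes tested, and 19 of 24 were lower when adjusted over the list alone.

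Interferon-stimulated genes rose in WT after pneumonia (median log2 fold change 0.55, 33 of 37 members positive, camera adjusted p = 5.8e-15; adjusted p = 0.255 with an estimated correlation). Adjusted over the list alone, 18 of the 37 were higher and none lower, and over all genes tested none passed. Oasl2 was counted at 10.8 ± 6.64 CPM in injured and 1.89 ± 0.793 CPM in control libraries, and Zbp1, a sensor of Z-form nucleic acid, at 13.4 ± 1.61 and 5.50 ± 1.42 CPM (SD, n = 4 each). WT injured 1 lay within the control range for Oasl2, at 2.28 CPM against 0.738 to 2.52 CPM, but above it for Zbp1, at 11.7 CPM against at most 6.83 CPM. Genes of the response to interferon gamma rose (median 0.65, 28 of 34 positive, adjusted p = 1.56e-10; adjusted p = 0.285 with an estimated correlation). Among them Gbp9, a guanylate-binding protein, was counted at 3.99 ± 1.99 and 0.690 ± 0.585 CPM, with WT injured 1 at 1.19 CPM within the control range of 0.197 to 1.53 CPM. Neutrophil markers rose (median 1.19, 21 of 24 positive, adjusted p = 3.24e-08; adjusted p = 0.285 with an estimated correlation). Their summed level was 923 ± 242 CPM in injured and 713 ± 79.8 CPM in control libraries (exact permutation p = 0.171, adjusted p = 0.411). WT injured 1 and 4, at 736 and 751 CPM, lay within the control range of 616 to 803 CPM. S100a8, a calcium-binding protein abundant in neutrophils, was counted at 33.0 ± 20.9 and 5.93 ± 3.18 CPM, and Slfn4 at 73.3 ± 69.5 and 7.75 ± 5.98 CPM. WT injured 1 stood apart for Slfn4 too, at 9.75 CPM against 91.5, 163 and 28.6 CPM in WT injured 2 to 4. Erythroid markers rose (median 2.14, 6 of 6 positive, adjusted p = 6.11e-07; adjusted p = 0.255 with an estimated correlation). Their summed level was 506 ± 162 CPM in injured and 80.7 ± 60.4 CPM in control libraries (ratio 6.28, exact permutation p = 0.0286, adjusted p = 0.114 over 12 marker lists). Beta-globin, listed as Beta-s, held most of it, at 389 ± 135 and 57.8 ± 40.5 CPM.

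Lists that fell by smaller amounts in WT were the lysosome and its proteases (median -0.13, 31 of 33 members negative, camera adjusted p = 9.27e-06; 0.486 with an estimated correlation), antioxidant genes (-0.31, adjusted p = 2.76e-05; 0.521 with an estimated correlation), the unfolded protein response (-0.20, adjusted p = 0.000341; 0.0841 with an estimated correlation) and the cell cycle (-0.23, adjusted p = 5.07e-07; 0.548 with an estimated correlation). Lipa, the lysosomal acid lipase, was counted at 1900 ± 430 CPM in injured and 2570 ± 336 CPM in control libraries, and Kif20a, a mitotic kinesin, at 18.1 ± 5.90 and 25.8 ± 3.62 CPM (SD, n = 4 each). Nuclear-encoded genes of oxidative phosphorylation rose (median 0.18, 28 of 35 positive, adjusted p = 0.017; adjusted p = 0.914 with an estimated correlation). WT injured 1 was highest for Cox6c, a subunit of complex IV, at 126 CPM, against 59.3 to 76.5 CPM in the other injured and 49.1 to 73.1 CPM in control libraries. The alveolar epithelium markers had a negative median (-0.29, camera adjusted p = 0.0231; adjusted p = 0.548 with an estimated correlation), although their summed level was higher in injured libraries, at 2710 ± 267 against 2320 ± 263 CPM. Lyz1, a lysozyme that macrophages also express, held most of that sum, at 2464 and 2082 CPM on average. Genes of alveolar macrophage identity had a median of -0.03 over 39 members (adjusted p = 0.996).

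By single genes, 0 of 12455 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, while 1334 had an unadjusted p under 0.05, against 623 given by chance. DESeq2 called 162 genes, limma voom 4649 with library quality weights and 0 with equal weights. The lowest p-values belonged to Nr1d1, a repressor in the circadian clock (31.5 ± 5 CPM in injured and 10.9 ± 2.09 CPM in control libraries, log2 fold change 1.43, SE 0.21, adjusted p = 0.0501), and Socs2, a suppressor of cytokine signalling (23.8 ± 6.41 and 11.1 ± 0.481 CPM, log2 fold change 0.99, SE 0.15, adjusted p = 0.0501). Rftn1, a lipid raft protein, at log2 fold change -0.71, Ffar2, a receptor of short-chain fatty acids, at 1.31 and Ovol2 at 1.64 each had an adjusted p of 0.0569. Without WT control 4 there were 7 calls and without WT injured 2 there were 10. With controls 1 and 2 as the only controls there were 1631, and with controls 3 and 4 only there were 63, settings chosen after the data were seen.

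In TLR3-KO macrophages the comparison of injured with control libraries called 136 genes, 72 higher and 64 lower (edgeR, adjusted p under 0.05). At least a 2-fold change was seen in 58 of them. Interferon-induced genes made up much of the top of the list. Ifit1, Ifit2 and Ifit3, which bind viral RNA or act beside its sensors, rose 10.4-fold, 9.83-fold and 9.84-fold. Ifit1 rose from 1.86 ± 0.258 to 20.3 ± 19.3 CPM (SD, n = 4 each; log2 fold change 3.38, SE 0.69, adjusted p = 0.0376). Chi3l1, a secreted chitinase-like protein, rose 35.8-fold (log2 fold change 5.16, SE 1.11, adjusted p = 0.0425), and Lcn2, which withholds iron by binding bacterial siderophores, rose 33.4-fold, from 0.712 ± 0.325 to 24.7 ± 22 CPM (adjusted p = 0.0425). These rises were uneven: Ifit1 was counted at 23.1, 3.55, 8.19 and 46.5 CPM, Lcn2 at 33, 3.72, 10.3 and 51.8 CPM and Chi3l1 at 34.3, 2.73, 11.2 and 41.6 CPM in TLR3-KO injured 1 to 4. Without TLR3-KO injured 4 the log2 fold change of Ifit1 was 2.59 (adjusted p = 0.066). Clec1b, a C-type lectin receptor, fell from 45.0 ± 53.1 to 7.63 ± 1.48 CPM, which rests on TLR3-KO control 3 at 124 CPM. Without that library its log2 fold change was -1.33 (adjusted p = 0.0951).

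The interferon-stimulated list rose (median log2 fold change 0.97, 34 of 37 members positive, camera adjusted p = 2.88e-12; adjusted p = 0.416 with an estimated correlation). Over all genes tested 11 of its members rose and none fell, and 21 rose when adjusted over the list alone. Besides the Ifit genes these included Oasl2 (log2 fold change 3.07, SE 0.64), Rtp4 (3.01, SE 0.63) and the nucleotide kinase Cmpk2 (3.27, SE 0.75). The Ifit genes, Oasl2, Rtp4 and Cmpk2 stayed called with RLE size factors, DESeq2 and the filter of at least 5 CPM in 3 libraries. They kept their direction but were not called with voom under either weighting, without a filter on low counts, in the fit of 2 groups or with the block. The interferon gamma list rose (median 0.79, 28 of 34 positive, adjusted p = 6.17e-09; adjusted p = 0.416 with an estimated correlation) and had 3 called members, Serpina3g at 3.94, Gbp6 at 1.99 and Gbp7 at 1.09 on the log2 scale. Gbp7 was counted at 31.8 ± 0.802 CPM in injured and 14.2 ± 4.95 CPM in control libraries. Inflammatory cytokine and NF-kB genes rose as a list (median 0.25, 27 of 36 positive, adjusted p = 0.013; adjusted p = 0.844 with an estimated correlation), of which Lcn2 alone passed over all genes; with controls 1 and 2 only the median was -0.023 (adjusted p = 0.555). Neutrophil markers rose (median 0.78, 21 of 24 positive, adjusted p = 4.68e-05; adjusted p = 0.416 with an estimated correlation), and their summed level was 972 ± 160 against 697 ± 54.4 CPM (exact permutation p = 0.0286, adjusted p = 0.229). Csf3r, the receptor of granulocyte colony-stimulating factor, was counted at 68.9 ± 24.2 and 23.6 ± 5.51 CPM with an adjusted p of 0.0553.

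MHC class II presentation fell in TLR3-KO after pneumonia (median -0.31, 13 of 16 members negative, camera adjusted p = 0.000439; adjusted p = 0.416 with an estimated correlation). H2-Aa fell from 414 ± 360 to 85.5 ± 36.6 CPM (log2 fold change -2.32, SE 0.51, adjusted p = 0.0425), H2-Eb1 from 251 ± 224 to 52.3 ± 17.7 CPM and H2-Ab1 from 648 ± 552 to 147 ± 59.5 CPM. The spread came from the controls, where H2-Aa was counted at 238, 146, 942 and 329 CPM in TLR3-KO controls 1 to 4. Without TLR3-KO control 3 the log2 fold changes of H2-Aa, H2-Eb1 and H2-Ab1 were -1.53, -1.49 and -1.42 (adjusted p = 0.117, 0.116 and 0.129). T cell markers moved beside them. All 22 members of that list were lower (median -1.37, adjusted p = 0.000771; adjusted p = 0.687 with an estimated correlation). Their sum was 248 ± 31.1 CPM in injured and 375 ± 92.6 CPM in control libraries (exact permutation p = 0.0571). Cd2 held most of that sum, at 226 ± 27.5 and 337 ± 76.6 CPM, so the sum says little about members counted at low levels. The fall of the list rests on TLR3-KO controls 3 and 4. Cd3g, a chain of the T cell receptor complex, was counted at 0.0474, 0.021, 2.49 and 1.56 CPM in TLR3-KO controls 1 to 4, and with controls 1 and 2 only the median of the list was 0.385 (adjusted p = 0.293).

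Other groups that fell were antioxidant genes (median -0.36, 22 of 25 negative, camera adjusted p = 4.89e-05; adjusted p = 0.448 with an estimated correlation) and cholesterol biosynthesis (median -0.37, 21 of 24 negative, adjusted p = 9.97e-07; adjusted p = 0.416 with an estimated correlation). Called members were Gstm1, a glutathione transferase, at -0.76 (SE 0.16), and Ftl1, the ferritin light chain, at -0.62 (SE 0.13). In cholesterol biosynthesis they were the mevalonate pathway enzymes Mvd at -0.51 (SE 0.11) and Pmvk at -0.77 (SE 0.17). Lipid handling fell slightly (median -0.12, adjusted p = 0.0235; adjusted p = 0.416 with an estimated correlation). Within it Apoe, a lipid carrier of macrophages, fell from 83.6 ± 27.5 to 37.3 ± 4.96 CPM (log2 fold change -1.24, SE 0.22, adjusted p = 0.0287). TLR3-KO controls 1 to 4, at 99.6, 58.8, 114 and 61.8 CPM, stood apart from the other groups. WT libraries, control and injured, lay between 29.7 and 46.6 CPM. Oxidative phosphorylation fell (median -0.19, adjusted p = 0.00197; adjusted p = 0.747 with an estimated correlation). Celf4, an RNA-binding protein, fell from 49.0 ± 9.41 to 22.2 ± 2.46 CPM (log2 fold change -1.20, SE 0.18), Rgs1, a regulator of G protein signalling, by 1.65 and Fkbp11, a prolyl isomerase of the endoplasmic reticulum, by 1.25 on the log2 scale. The cell cycle list rose (median 0.50, 38 of 41 positive, adjusted p = 2.72e-08; adjusted p = 0.484 with an estimated correlation), and alveolar epithelium markers rose (median 0.66, adjusted p = 0.00197; adjusted p = 0.416 with an estimated correlation), both without a member called over all genes. The summed level of the epithelium markers ran the other way, at 2370 ± 173 CPM in injured and 2590 ± 520 CPM in control libraries (exact permutation p = 0.457). In WT most of that sum was Lyz1, which macrophages also express, so it says little about members counted at low levels. The Y-linked list rose (median 2.14, adjusted p = 0.000232; adjusted p = 0.416 with an estimated correlation), beside the Xist counts of the TLR3-KO controls.

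The count of 136 moved with single libraries. It was 35, 1238, 6 and 11 without TLR3-KO control 1, 2, 3 and 4 in turn, and 4, 23, 0 and 21 without TLR3-KO injured 1, 2, 3 and 4. With the replicate number as a block, 11 genes were called, and of the 16 genes with the largest changes Celf4 alone was among them. With TLR3-KO control 4, which lacks Xist, as the only control, 6 genes were called, and with the share of female RNA as a covariate, 0 were. All 16 of the genes with the largest changes kept their direction in both fits. With TLR3-KO control 4 alone this was all but fixed, since the genes were named for no overlap between injured and control libraries. The covariate, with female shares of 99.6%, 99.4%, 88% and 0% in TLR3-KO controls 1 to 4, leaves nearly the same contrast. The kept direction therefore decides nothing about sex.

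The genotypes were next compared in controls. Besides Tlr3 (log2 fold change -2.76, SE 0.33, adjusted p = 0.000745), TLR3-KO macrophages differed most surely in Wdfy1, an endosomal FYVE-domain protein, counted at 13.8 ± 3.07 CPM against 69.2 ± 3.44 CPM in WT (SD, n = 4 each; log2 fold change -2.41, SE 0.13, adjusted p = 3.42e-08), and in genes of chromosome 8. Mtmr7, a phosphoinositide phosphatase, was 4.04-fold lower (adjusted p = 3.25e-07), Hgsnat, a lysosomal acetyltransferase, was 2.98-fold lower and Mfhas1 was 2.77-fold higher (adjusted p = 1.95e-06 each). Gsr, the glutathione reductase, was counted at 381 ± 156 and 941 ± 250 CPM (log2 fold change -1.38, SE 0.23, adjusted p = 0.0139). In all, edgeR called 82 genes, 31 higher and 51 lower in TLR3-KO, 33 of them at least 2-fold apart. Departures from the group mean matched by replicate number across the control genotypes, although the labels state no pairing. The division of controls 1 and 2 from 3 and 4 in both genotypes could give part of that match. With the number as a block 31 genes were called, 16 higher and 15 lower.

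Other genes higher in TLR3-KO controls were Mid1 (log2 fold change 1.84, SE 0.39), Wfdc10 (1.73, SE 0.34), Arhgap22 (1.49, SE 0.26), the adenylate cyclase Adcy4 (1.36, SE 0.24), the kallikrein Klk8 (1.34, SE 0.28), Wwc2 (1.27, SE 0.26) and Gpd1, a glycerol phosphate dehydrogenase (1.23, SE 0.22). Lower were Erdr1 (-3.06, SE 0.33), a multicopy gene whose counting is uncertain and which had no position, Osbpl3 (-1.41, SE 0.27), Ppp1r3b (-1.10, SE 0.14) and the membrane protease Adam17 (-0.98, SE 0.20). With the block, 10 of the 16 most changed genes stayed called; Mid1, Arhgap22, Adcy4, Wwc2, Osbpl3 and Adam17 did not.

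Several gene groups differed between the control genotypes. Cholesterol biosynthesis was lower in TLR3-KO (median -0.35, 18 of 24 negative, camera adjusted p = 1.48e-06; adjusted p = 0.462 with an estimated correlation). Dhcr7, which makes cholesterol in the last step, was counted at 62.2 ± 9.44 against 111 ± 19.3 CPM (log2 fold change -0.91, SE 0.12, adjusted p = 0.00137), and Hsd17b7 was also called (-0.69, SE 0.14). Oxidative phosphorylation was higher (median 0.33, 33 of 35 positive, adjusted p = 5.21e-06; adjusted p = 0.791 with an estimated correlation). Inflammatory cytokine and NF-kB genes were lower (median -0.67, 31 of 36 negative, adjusted p = 0.000765; adjusted p = 0.794 with an estimated correlation). Tnfaip3, an inhibitor of NF-kB signalling, was counted at 107 ± 37.6 against 203 ± 85.0 CPM. WT controls 1 and 2 stood apart for this list, with Nlrp3 at 141 and 127 CPM against 18.4 and 28.3 CPM in WT controls 3 and 4. With controls 1 and 2 of both genotypes only its median was -0.90, and with controls 3 and 4 only it was 0.005 (adjusted p = 0.911). MHC class II genes were higher (median 0.74, 12 of 16 positive, adjusted p = 0.00159; adjusted p = 0.462 with an estimated correlation), as were T cell markers (median 1.04, 22 of 22 positive, adjusted p = 0.0195; adjusted p = 0.794 with an estimated correlation) and dendritic cell markers (median 0.46, adjusted p = 0.00903; adjusted p = 0.486 with an estimated correlation). TLR3-KO control 3 stood apart for MHC class II, with H2-Aa at 942 CPM against 238, 146 and 329 CPM in TLR3-KO controls 1, 2 and 4. With controls 1 and 2 of both genotypes only, the median of the T cell list was 0.127 (adjusted p = 0.983) and Cd3g was lower in TLR3-KO (log2 fold change -1.54, adjusted p = 0.452). Genes of alternative activation were higher (median 0.35, adjusted p = 0.0344; adjusted p = 0.462 with an estimated correlation), Socs2 being called at 0.77 (SE 0.15). Lower lists were the unfolded protein response (-0.22, adjusted p = 0.00903; 0.462 with an estimated correlation), pattern recognition receptors (-0.15, adjusted p = 0.0235; 0.752 with an estimated correlation), interferon-stimulated genes (-0.28, adjusted p = 0.0344; 0.794 with an estimated correlation), MHC class I presentation (-0.17, adjusted p = 0.0344; 0.791 with an estimated correlation) and lysosomal genes (-0.015, adjusted p = 0.0344; 0.794 with an estimated correlation). The ceramidase Asah1, a lysosomal enzyme encoded within 10 Mb of Tlr3, was called at -0.59 (SE 0.11). The Y-linked list was lower (-2.17, adjusted p = 5.48e-05; 0.462 with an estimated correlation).

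The count of 82 fell to 11 with TLR3-KO control 4 as the only TLR3-KO control and to 5 with the share of female RNA as a covariate; Mfhas1, Wdfy1, Mtmr7 and Hgsnat were called in both. It was 18, 17, 414 and 39 without WT control 1, 2, 3 and 4, and 30, 466, 46 and 46 without TLR3-KO control 1, 2, 3 and 4.

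In injured mice, where none of the libraries held Xist above 0.14 CPM, 75 genes differed by genotype, 47 higher and 28 lower in TLR3-KO, and 52 of them at least 2-fold. Tlr3 (-2.83, SE 0.34, adjusted p = 0.000558), Wdfy1 (-2.46, SE 0.13, adjusted p = 2.7e-08) and Mtmr7 (-2.40, SE 0.13, adjusted p = 3.07e-08) were again lower. Msr1, a scavenger receptor that takes up modified lipoproteins and bacteria, was counted at 135 ± 6.76 CPM in TLR3-KO and 42.9 ± 7.78 CPM in WT (SD, n = 4 each; 3.09-fold, adjusted p = 0.000111). Sftpb, which encodes a surfactant protein, was higher in TLR3-KO, although at a low level, at 2.31 ± 0.762 against 0.323 ± 0.0601 CPM (6.92-fold, adjusted p = 0.00543).

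Alveolar epithelium markers were higher as a list (median log2 fold change 1.02, 16 of 21 positive, camera adjusted p = 5.09e-09; adjusted p = 0.198 with an estimated correlation). Called members were Sftpb, Sftpd (2.22, SE 0.44), the surfactant protein Sftpa1 (1.60, SE 0.33) and the water channel Aqp5 (2.27, SE 0.45), and 11 members were higher when adjusted over the list alone. The summed level of the whole list was lower, at 2370 ± 173 CPM in TLR3-KO and 2710 ± 267 CPM in WT (exact permutation p = 0.114). Lyz1, which macrophages also express, held most of the WT sum, so it says little about members at low levels such as Sftpb. Gprc5a (2.30, SE 0.40), the matricellular gene Cyr61 (2.27, SE 0.34) and Emp2 (2.14, SE 0.43) were also higher, as were Adcy4 (1.66, SE 0.24), Wwc2 (1.63, SE 0.26) and Mfhas1 (1.60, SE 0.11). Cell cycle genes were higher (median 0.71, 40 of 41 positive, adjusted p = 1.05e-25; adjusted p = 0.293 with an estimated correlation). Kif20a was called, at 38.7 ± 5.77 against 18.1 ± 5.90 CPM (1.06, SE 0.21, adjusted p = 0.035), and 32 members were higher when adjusted over the list alone, among them Cdc20, which activates the anaphase-promoting complex (34.7 ± 5.60 against 17.4 ± 4.81 CPM). Phagocytosis and efferocytosis genes were higher (median 0.28, 20 of 30 positive, adjusted p = 0.0275; adjusted p = 0.656 with an estimated correlation), Msr1, which lies within 10 Mb of Tlr3, being the called member, and complement genes were higher (0.22, 16 of 17 positive, adjusted p = 0.0475; adjusted p = 0.97 with an estimated correlation).

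Erythroid markers were lower in injured TLR3-KO libraries (median -1.99, 6 of 6 negative, adjusted p = 0.00414; adjusted p = 0.681 with an estimated correlation). Their sum was 125 ± 62.0 against 506 ± 162 CPM (exact permutation p = 0.0286, adjusted p = 0.343). Antioxidant genes were lower (-0.22, adjusted p = 0.016; adjusted p = 0.978 with an estimated correlation), Gsr being called at 310 ± 15.2 against 805 ± 165 CPM (-1.40, SE 0.23). MHC class I presentation was lower (-0.19, adjusted p = 0.0246; adjusted p = 0.887 with an estimated correlation). Among single genes Erdr1 (-3.86, SE 0.34), Hgsnat (-1.13, SE 0.12), the pyruvate dehydrogenase kinase Pdk4 (-0.86, SE 0.15) and the chemokine receptor Cxcr1 (-0.83, SE 0.18) were lower, while the neutrophil collagenase Mmp8 was higher (1.07, SE 0.21). The count of 75 was 30, 17, 20 and 439 without WT injured 1, 2, 3 and 4, and 18, 16, 19 and 75 without TLR3-KO injured 1, 2, 3 and 4.

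**Figure D3:**
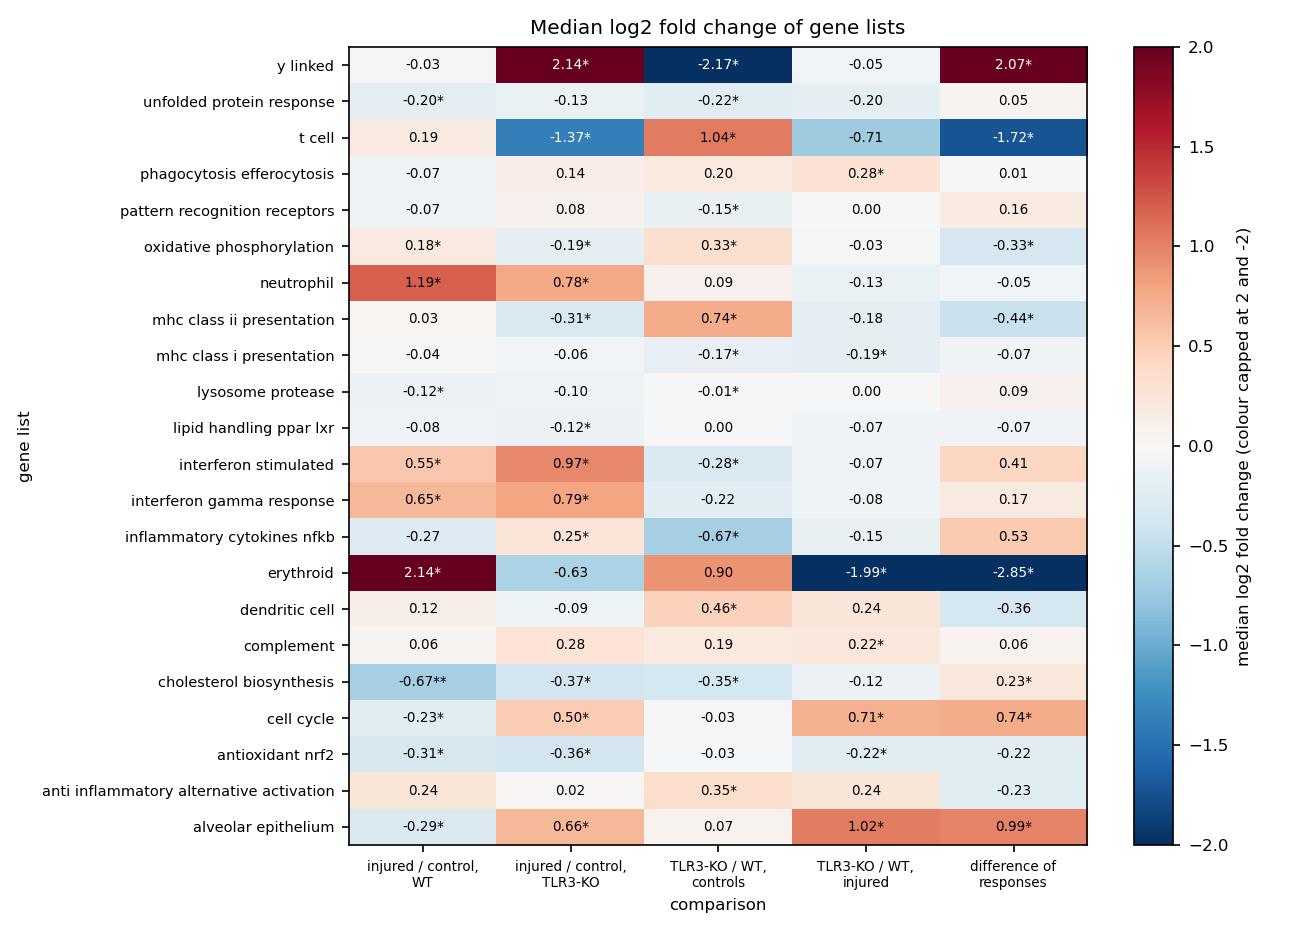
Median log2 fold change of each gene list (y axis) in each comparison (x axis), for the lists that passed in at least 1 comparison; * marks a camera adjusted p under 0.05 with the preset correlation and ** one that also held with an estimated correlation. Interferon and neutrophil lists are positive after pneumonia in both genotypes, and ** appears for cholesterol biosynthesis in WT.

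The genotype effects in the 2 states shared 19 genes, 9 higher and 10 lower in TLR3-KO in both, where independent lists of these sizes would share 0.117 and 0.115. They were Tlr3, Wdfy1, Mtmr7, Mfhas1, Hgsnat, Gsr, Wwc2, Fut10, Efha2, Leprotl1 and 4930444A02Rik, of which all but Wdfy1 lie on chromosome 8, and Erdr1, Adcy4, Arhgap22, Dbp, Dhcr7, Cd59a, Cd101 and Gm6498, named after their values were seen. Within 10 Mb of Tlr3, 7 of the 46 other genes tested were called in controls, against 73 of 12230 elsewhere (odds ratio 29.8, Fisher's exact p = 1.67e-08), and 9 of 46 were called in injured mice, against 64 of 12230 (odds ratio 46.2, p = 5.16e-12). On the whole of chromosome 8, 15 genes besides Tlr3 were called in controls and 16 in injured mice, 9 of them in both, and 21 of the 22 had the same direction in both states. Neither pneumonia comparison called a gene within 10 Mb of Tlr3, which decides nothing. The one in WT called none anywhere, and the one in TLR3-KO called only 1.11% of genes elsewhere, too few to expect calls among 46.

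**Figure D4:**
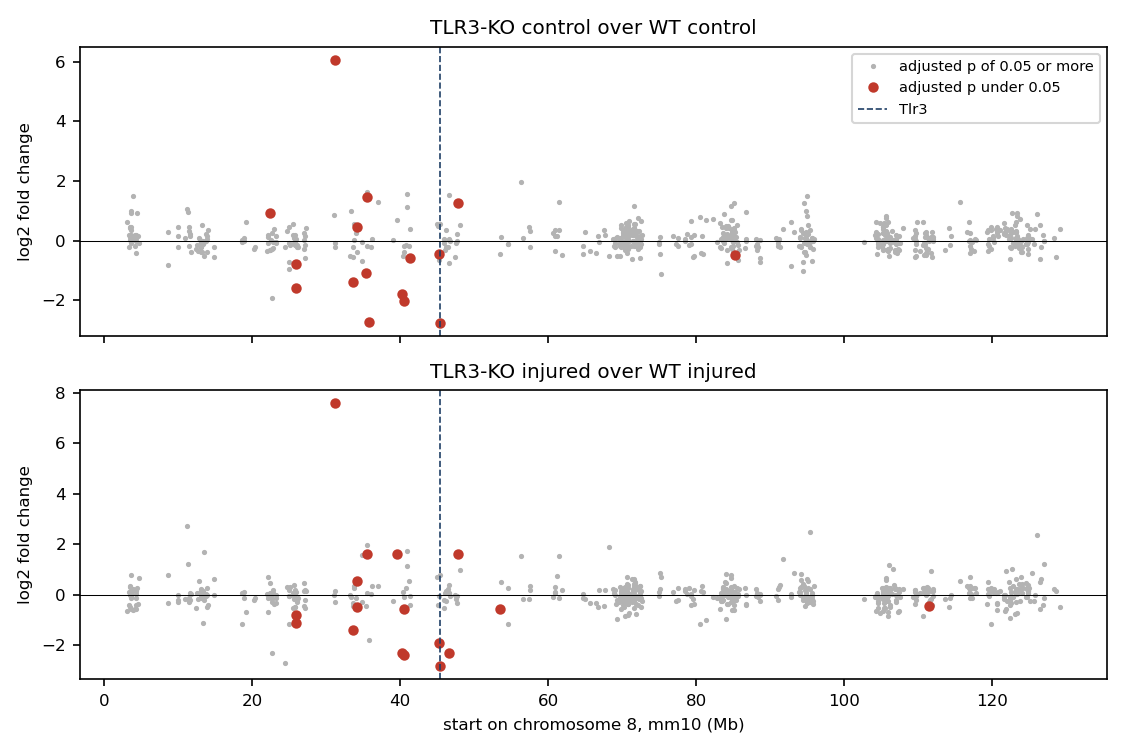
Log2 fold change of TLR3-KO over WT for the genes tested on chromosome 8, by start position in Mb (mm10), in controls (top) and in injured mice (bottom); red points have an edgeR adjusted p under 0.05 and the dashed line marks Tlr3. Most of the 15 and 16 called genes lie to the left of Tlr3 or close to it.

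The last comparison asked whether the response to pneumonia differed by genotype. No gene passed (0 of 12455 in edgeR, lowest adjusted p = 0.237), while 2209 had an unadjusted p under 0.05. DESeq2 called 109, limma voom 5087 with quality weights and 0 with equal weights. The lowest p-values belonged to Gata3, a transcription factor of lymphoid cells (-2.68, SE 0.51), the tight junction gene Cldn18 of lung epithelium (2.75, SE 0.54), Snhg8 (-2.10, SE 0.43), Sftpb (2.68, SE 0.57) and Gm11545 (-1.36, SE 0.29). As lists, the responses differed for the cell cycle (median difference 0.74, 40 of 41 positive, camera adjusted p = 2.54e-14; adjusted p = 0.785 with an estimated correlation) and alveolar epithelium (0.99, adjusted p = 0.000161; adjusted p = 0.785 with an estimated correlation), which responded more positively in TLR3-KO. They also differed for erythroid markers (-2.85, adjusted p = 0.00288; adjusted p = 0.813 with an estimated correlation), T cell markers (-1.72, adjusted p = 0.00158; adjusted p = 0.813 with an estimated correlation) and MHC class II presentation (-0.44, 16 of 16 negative, adjusted p = 0.00342; adjusted p = 0.785 with an estimated correlation), which responded more negatively. The size for erythroid markers rests on TLR3-KO control 4, where they summed to 509.1 CPM against 124.2, 42.3 and 64.3 CPM in TLR3-KO controls 1 to 3. Without it the difference was -1.66 (adjusted p = 0.0259), and the list median after pneumonia in TLR3-KO turned from -0.63 to 0.69. The T cell and MHC class II lists were also uneven among TLR3-KO controls 1 to 4. Cd3g was counted there at 0.0474, 0.021, 2.49 and 1.56 CPM, and H2-Aa at 238, 146, 942 and 329 CPM. Interferon-stimulated genes did not pass (0.41, adjusted p = 0.319). The pneumonia responses shared 0 called genes because WT had none; of the 136 genes called in TLR3-KO, 111 had the same direction in WT. Over all 12455 genes, which are not independent of each other, the responses correlated weakly (Pearson 0.19, Spearman -0.09).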

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

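The tests of female RNA by escape genes and of calls near Tlr3 were set before their results were seen; the explanations weighed for the calls near Tlr3 and the other tests of this part were chosen only after the results were seen. T cell RNA in the controls was tested in 3 ways: the first was void because it measured genes in the libraries they were chosen from, the next, against the alveolar macrophage identity list, decided in TLR3-KO (-0.78 against -0.33) but not in WT (-0.38 against -0.21), and the last is given below.

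Of 64 groups of 4 libraries tested for a library far from the others, 4 had one, where chance gives about 1 in 20 groups, or 3.2. Y-linked genes summed to 169 CPM in TLR3-KO control 4 and to between 0.76 and 23.2 CPM in the other TLR3-KO controls. Markers of monocyte-derived macrophages summed to 14500 CPM in TLR3-KO control 4 and to between 12300 and 12700 CPM in the others. Markers of eosinophils, mast cells and basophils summed to 2.83 CPM in WT control 1, against 1.06 to 1.32 CPM, and alveolar epithelium markers to 1930 CPM in WT control 4, against 2440 to 2470 CPM.

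The response of 8 gene lists to pneumonia differed between the genotypes by the test of the difference itself with the preset correlation. Median log2 differences, TLR3-KO minus WT, were 0.994 for alveolar epithelium, 0.74 for the cell cycle, 0.234 for cholesterol biosynthesis and 2.07 for Y-linked genes. They were -2.851 for erythroid markers, -1.721 for T cell markers, -0.439 for MHC class II presentation and -0.332 for oxidative phosphorylation. With an estimated correlation the adjusted p lay between 0.785 and 0.813 for these lists.

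Whether chance can be excluded was tested by counting other splits of the libraries. After pneumonia in TLR3-KO the real groups of unpaired libraries gave 136 calls and the other splits at most 0 (1 of 35 as large). This is the smallest share that 35 splits allow. It was not adjusted over the comparisons, so it argues against chance but does not exclude it. The real groups also set the controls that hold Xist on one side. The numbers may pair the TLR3-KO libraries, for which 6 of 8 matches spoke. If so, the 8 splits that part all 4 numbers are too few for a share under 0.05 (136 calls, highest other 0). The blocked count was 11. For genotype in injured mice the real groups gave 75 calls and the other splits at most 1 (1 of 35), again the smallest share possible. The split by genotype must part Tlr3 and genes near it, and 17 of the 75 calls lie on chromosome 8. The count therefore decides nothing about the calls elsewhere. In WT after pneumonia (0 calls, highest other 50, 35 of 35) and for the difference of the responses (0 calls, highest other 7, 100 of 100) the splits decide nothing, since every split calls at least 0 genes. For genotype in controls chance cannot be excluded by this count alone, with 82 calls and 3 of 35 splits as large. Still, 19 of these genes were called with the same direction between the injured genotypes, which share no library with the controls. Tlr3 and 9 others of the 19 lie on chromosome 8. The highest other split, with 4293 calls, set controls 1 and 2 of both genotypes against controls 3 and 4, which points to a structure of the samples. The next, with 2311 calls, set WT controls 1, 2 and 4 and TLR3-KO control 2 against the rest and follows that division only in part. The blocked count was 31. Of the 8 splits of the controls that part all 4 numbers, the real one called 82 and the highest other 0, and 8 splits are too few for a share under 0.05.

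For Xist in TLR3-KO controls 1, 2 and 3, expression in male cells is excluded by their Y-linked counts, at most 12% of the median library where the lowest other library reached 84.3%, and a swap with WT libraries is excluded by Tlr3, at most 0.717 CPM where the lowest WT library had 2.18 CPM. Genes that escape X inactivation were 0.35 higher on the log2 scale (4 genes, exact permutation p = 0.0964), of which Eif2s3x (0.50, exact p = 0.00536) and Kdm6a (0.49, exact p = 0.0143) passed alone, without adjustment, and Kdm5c and Ddx3x did not. That test leaves female mice open, while the Y-linked counts of TLR3-KO controls 1 and 2, at 0.4% and 0.6%, go with female RNA. In TLR3-KO control 3 the Y-linked genes lay at 10.2% to 14.3% of the male median, consistent with RNA of both sexes in 1 library. Whether sex caused the 136 calls after pneumonia cannot be told apart from an effect of infection: their median log2 change was 0.97 against TLR3-KO control 4 alone and 0.86 against all 4 controls, but that library took part in choosing the genes and is the only TLR3-KO control without Xist.

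Controls 1 and 2 lay apart from controls 3 and 4 in both genotypes, and library size is argued against by its ratio between them, 0.987 in TLR3-KO and 1.34 in WT. Immediate early and stress genes summed to at least 4670 CPM in controls 1 and 2 and at most 3790 CPM in controls 3 and 4. The members of this list did not move alike. Egr1 was higher in controls 1 and 2 of both genotypes, while Fos, Btg2 and Dnajb1 were higher in controls 3 and 4 of both. T cell RNA as the whole cause is argued against, since the median log2 falls of -0.78 in TLR3-KO and -0.38 in WT, over genes called lower in controls 3 and 4 of the other genotype, would need T cells for 41.8% and 23.2% of the RNA. The 25 T cell markers would then have a median of only 2.44 CPM in T cells by the TLR3-KO controls (95% bootstrap interval 1.82 to 4.63) and 1.45 CPM by the WT controls (0.812 to 2.19), where the median gene tested had 20 and 19.2 CPM in controls 3 and 4; a smaller part stays open. A stress response of the cells before lysis and a separate day of collection cannot be told apart, because the division was taken from these libraries and the labels give no dates. No biological explanation other than T cell RNA and this stress response was examined.

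Genotype calls gathered near Tlr3, with an odds ratio of 29.8 in controls and 46.2 in injured mice. The sex of the TLR3-KO control RNA as their cause is excluded by the value of 46.2 between injured groups, which hold no control library. Loss of TLR3 acting on genes wherever they lie would not lead to calls for 19.6% of genes near Tlr3 against 0.523% elsewhere in injured mice. Sequence of another strain carried along with the knocked-out allele may account for these calls, and neither its extent nor any variant was examined. Effects of TLR3 on single genes of this region stay open.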

How the results depend on the processing

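The female share, male control, control subset, control division and equal-weight settings, and the overlap of genotype effects, were chosen after seeing the data. In this order, calls are for pneumonia in WT, pneumonia in TLR3-KO, genotype in controls, genotype in injured mice and the difference of responses, 0, 136, 82, 75 and 0 as reported. RLE size factors gave 11, 139, 147, 77 and 0, DESeq2 162, 1003, 767, 422 and 109, and limma voom with quality weights 4649, 1734, 2894, 5296 and 5087. With equal weights voom gave 0, 92, 102, 59 and 0, so its larger counts came with the weights, which lay between 0.28 and 3.66. No filter on low counts gave 1, 44, 64, 64 and 0, and at least 5 CPM in 3 libraries 2, 182, 86, 39 and 0. Fits of only the 2 groups gave 0, 33, 10 and 154 for the first 4. The replicate number as a block gave 3, 11, 31, 21 and 0. The cause was not tested for these. Leaving out each library gave 0 to 10, 0 to 1238, 17 to 466, 16 to 439 and 0 to 0. The overlap of pneumonia responses, 0 as reported, was 53 with DESeq2 and 1 with the block, and that of genotype effects, 19 as reported, was 67 and 12.

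With the female share as covariate the counts were 13, 0, 5, 80 and 0, where the share takes up most of the contrast with TLR3-KO controls. Eif2s3y then had a log2 fold change of -0.38 after pneumonia in TLR3-KO and -0.37 in the difference of responses, and Ddx3y 0.11 between control genotypes and -0.11 in the difference. The Y-linked list then had a median of 0.156 after pneumonia in TLR3-KO and 0.077 in the difference. With TLR3-KO control 4 as the only TLR3-KO control, assumed to vary like the other libraries, 6 genes were called after pneumonia in TLR3-KO and 11 between control genotypes. Eif2s3y was then at -0.11 and, in the difference, -0.09, and Mgl2 between control genotypes at -0.06. With controls 1 and 2 only, the counts were 1631, 83 and 237, and 57 for the difference. After pneumonia in TLR3-KO Icos was then at 0.34, the inflammatory list at -0.023 and the T cell list at 0.385, and Cd3g between control genotypes at -1.54. With controls 3 and 4 only, the counts were 63, 4108 and 20. With the control division as covariate 1276 genes were called between control genotypes. The cause was not tested for the control subsets. Across settings, named genes gave the same call 4195 times, a stronger one 441, a weaker one 489 and the other direction 9 times. For genes, the same call includes those that passed in neither fit, so these counts do not measure how many called genes stayed called. Of the 16 genes with the largest changes after pneumonia in TLR3-KO, 16 stayed called with RLE size factors and with DESeq2. In the fit of 2 groups 4 did, and with the block 1. Gene lists gave the same call 228 times, a weaker one 113 and the other direction 4 times. Depth limits genes such as Tlr3, with 13 to 34 counts in TLR3-KO libraries.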

Other observations

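The test of this part was chosen only after the result was seen. Nr1d1 had the lowest p-value after pneumonia in WT, and other genes of the circadian clock moved with it without passing in edgeR: Dbp by 1.01, Per2 by 0.88, Per1 by 0.41 and Arntl, which peaks at the opposite phase, by -0.44 on the log2 scale. A score of 6 genes of its phase minus 3 of the opposite phase, without Nr1d1, was -1.13 ± 0.30 in injured and -1.85 ± 0.09 in control WT libraries (SD, n = 4 each), a difference of 0.72 (exact permutation p = 0.0286, the smallest possible). It differed by 0.06 after pneumonia in TLR3-KO (exact p = 0.571), by 1.36 between control genotypes and by 0.70 between injured genotypes (exact p = 0.0286 each). Another time of day of collection may account for the difference of 0.72 in WT. Nr1d1 itself also rose in TLR3-KO (1.10, SE 0.21, edgeR adjusted p = 0.0366), where the score did not follow. There Per2 (0.67), Dbp (0.47), Nr1d2 (0.28) and Nfil3 of the opposite phase (-0.66) moved with it. Per1 (-0.39), Per3 (-0.4), Tef (-0.23) and, of the opposite phase, Arntl (0.34) and Clock (0.39) moved against it. A mean over genes that moved both ways cannot decide whether time of day was the sole cause of its rise. The labels give no times, and an effect of infection or genotype on the clock itself stays open.

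Rn45s, the precursor of ribosomal RNA, was counted at 8058, 4518, 5080 and 1065 CPM in WT injured 1 to 4 and at 5315 CPM in TLR3-KO control 4, against 960 to 2020 CPM in WT controls and 1320 to 2520 CPM in the other TLR3-KO libraries. The rise in 3 WT injured libraries goes beside the changes after pneumonia in WT (log2 fold change 1.71, edgeR adjusted p = 0.206), and whether those changes follow it was not tested.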
